A study of Homo sapiens with 15 samples.

How the data were processed

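RNA sequencing libraries of HT1080 cells, an established human fibrosarcoma line, were compared between 4 groups of samples. Per the labels, in 4 samples the cells' own KDAC4 (gene HDAC4) carried H803A, in 4 samples KDAC4 carried H976Y, in 4 samples KDAC7 (gene HDAC7) carried H709A, and 3 samples were wild-type cells given 1 µM TMP195 for 2 days. KDAC4 and KDAC7 are class IIa lysine deacetylases, and TMP195 is an inhibitor of that class. The series describes its variants as inactivated or enhanced. H803A and H709A are taken here as the inactive forms named in its title, and H976Y as the enhanced form, because replacing this histidine by tyrosine is known to raise the catalytic activity of class IIa enzymes. The variant cells received no treatment. Untreated wild-type cells belong to another series and were not used here. Per the labels' protocols, all samples were handled alike: cells were pelleted and frozen, total RNA was extracted, its quality was checked by electrophoresis, and ribosomal RNA was depleted before paired-end sequencing.

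The authors deposited 1 table of expected counts per gene, with 60675 genes and a column per sample. Trimmomatic 0.39, Bowtie2 2.4.5, RSEM 1.3.3 and DESeq2 1.38.2 are named with the build GRCh38, per the submitters' processing notes, which give no roles. RSEM estimates counts by sharing reads among the transcripts they match, so the values need not be whole and the values of near-identical genes are uncertain. The annotation release, the strand setting and any filter are not given in the sources used here. Reads from a gene and from an antisense or overlapping neighbour could therefore not be told apart. The deposited expected counts were not scaled between libraries.

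The deposited column of KDAC4 H803A replicate 4 does not hold counts. Among 7608 genes with a single annotated transcript longer than 1000 bases, its value equalled the transcript length minus 248.86 bases, within 0.02 bases, for 7363 genes, or 96.8%. The largest share of genes at any single difference was at most 0.237% in the other columns. Its values correlated with log2 transcript length at r = 0.949 across genes, and 50862 genes had a value above 5. RSEM writes such effective gene lengths beside its expected counts. This column was therefore left out, which leaves 3 libraries of KDAC4 H803A and 14 count libraries in all. The plan had been to fit 15 samples; a fit that reads all 15 columns as counts was run as an alternative.

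Expected counts were rounded to whole numbers. Gene IDs were matched by identifier to GENCODE v29 on GRCh38 (57055 matched) and to a table of gene names (56558 matched), and coordinates are those of that annotation, counted from 1. No gene lacked a name, and 0 columns of values were left unmapped to a sample. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17780 genes. Libraries were scaled by TMM. All groups were fitted in 1 model without covariates, so that they share the estimate of the spread, and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The common dispersion was 0.179 and the prior degrees of freedom 3.32. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Values per gene are counts per scaled library size (CPM, the usual unit of 1e+06 counts), given as mean ± SD with n = 3 for KDAC4 H803A, n = 4 for KDAC4 H976Y, n = 4 for KDAC7 H709A and n = 3 for TMP195; a value after ± beside a log2 fold change is its SE.

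The comparisons were KDAC4 H803A against KDAC4 H976Y, KDAC7 H709A against KDAC4 H803A, KDAC7 H709A against KDAC4 H976Y, TMP195 against the mean of the 3 variants, and TMP195 against each variant. A gene was counted as set apart in a group when all 3 pairwise comparisons of that group passed in one direction. The groups, the comparisons, the tests, the gene lists, the rule for named genes and 22 alternatives were fixed before the data were examined; 3 alternatives were added afterwards. The labels do not say that the samples of a group came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical. Total counts ran from 6151417 to 24297525, and scaled library sizes were such that 1 CPM stands for 4.86 to 23.9 counts. Intervals and lower bounds of fold changes cover counting error only: against a group with no counts the bound sets 3 counts over the whole group, and against a group with 1 to 3 counts the ratio is given with its 95% counting interval.

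The 25 gene lists held 658 genes, of which 654 matched the table. They cover lysine deacetylases and corepressor subunits, MEF2 factors and MEF2-regulated genes, myogenic and contractile genes, chondro-osteogenic genes, collagens and matrix glycoproteins, matrix proteases and inhibitors, integrins and cadherins, TGF-beta and SMAD targets, cell cycle and DNA replication, p53 targets, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, immediate early genes, hypoxia and glycolysis, cholesterol synthesis and SREBP2 targets, the amino acid and unfolded protein responses, NRF2 targets, HOX genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, and markers of epithelial, endothelial, blood and neural cells. Each list was tested in the first 4 comparisons, 100 tests in all, with limma's camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 25 lists within a comparison. The tests were repeated with an estimated correlation and with fry. With an estimated correlation no list passed in any of the 4 comparisons. Members with no counts on one side did not alter any list median when set at their bound.

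Named genes were taken by rule: HDAC4 and HDAC7; per comparison, the 8 highest and 8 lowest fold changes among called protein-coding genes whose sides did not overlap and whose higher side reached 5 CPM; up to 4 called members of each list with the largest fold changes and a mean of at least 1 CPM; and up to 4 genes set apart in each direction per group. Genes linked to the Y chromosome and XIST were left out. Of the genes this rule takes, those named in the text are mainly ones whose calls held with each library left out in turn and under each other alternative, the reading of all 15 columns excepted. That choice among them was made after their values were seen. Some genes that the rule takes are not reported here.

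Each computing step was tested on simulated counts drawn from the libraries' means and sizes, with 50 genes changed at each of 4 sizes. For KDAC4 H803A against KDAC4 H976Y (17255 genes) 12% of genes changed 2-fold, 74% changed 4-fold and 94% changed 8-fold were recovered, with 3 unchanged genes called. For KDAC7 H709A against KDAC4 H976Y (17142 genes) the shares were 14%, 72% and 96%, with 0 unchanged genes called. For TMP195 against the mean of the variants (17200 genes) they were 30%, 80% and 100%, with 6 unchanged genes called. None of the 50 genes changed 1.5-fold was recovered in the first comparison and 2% in the last. Low genes were not tested apart. A simulated raised list was called and none of the other lists was. Genes varied independently in this simulation, so it does not show how often lists are called where genes vary together. A simulated GC trend gave 5691 calls among 17108 genes, and 0 after the offsets described next.

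Alternatives were DESeq2's size factors in edgeR, the DESeq2 Wald test (DESeq2 1.42.0), scaling without the 20 most abundant genes, no filter on low counts, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and the 3 added after the data were seen: offsets for GC content and transcript length in 20 bins each (99.2% of tested genes had a GC value), all 15 columns read as counts, and the offsets with the library labelled KDAC4 H803A replicate 1 left out. Correlations of fold changes against the shared KDAC4 H976Y libraries were set beside 200 simulations of unchanged groups and beside splits of those libraries. Library composition, a GC trend (the difference in median log2 deviation between genes with at least 60.1% and at most 38.9% GC, among 9850 expressed genes), the overdispersion of each pair of libraries relative to Poisson counting over genes with 200 to 5000 counts, and medians per chromosome over 9843 expressed genes were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. No library was regrouped.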

Results

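Ribosomal-RNA-depleted total RNA was sequenced from HT1080 cells, a human fibrosarcoma line, whose own KDAC4 or KDAC7 gene carried a single amino acid change, and from wild-type cells given TMP195. KDAC4 and KDAC7 are class IIa lysine deacetylases, which bind MEF2 transcription factors and bring corepressor complexes to chromatin. TMP195 occupies the catalytic site of that class. Count libraries numbered 3 for KDAC4 H803A (inactive), 4 for KDAC4 H976Y (enhanced), 4 for KDAC7 H709A (inactive) and 3 for wild-type cells with 1 µM TMP195 for 2 days. Total counts were 15640844, 9189283 and 8909859 for KDAC4 H803A and 6151417 to 11343873 for KDAC4 H976Y. They were 9982033 to 24297525 for KDAC7 H709A and 12791994 to 14699009 for TMP195.

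The variants are point changes in the coding sequence, so the level of the targeted transcripts does not check the labels. HDAC4 (ENSG00000068024, chromosome 2, 239048168 to 239401654 on GRCh38) stood at 31.3 ± 12.1 CPM in KDAC4 H803A, 17.1 ± 3.14 in KDAC4 H976Y, 17.6 ± 16.2 in KDAC7 H709A and 23.7 ± 1.69 in TMP195-treated cells. In the 4 KDAC7 H709A libraries it had 40.1, 7.29, 4.45 and 18.5 CPM. The 19 expressed genes of chromosome 2 beyond 240 Mb lie next to HDAC4 and do not include it. Their median deviations there (log2, GC and length trends removed) were 0.34, -0.98, -0.99 and 0.05. This window was chosen after the values were seen. HDAC4 was not called in any of the 4 main comparisons (adjusted p = 0.278 for KDAC4 H803A against KDAC4 H976Y, 0.634, 0.977 and 0.876 for the others). HDAC7 (ENSG00000061273, chromosome 12, 47782722 to 47833132) stood at 202 ± 13.1 CPM, 69.1 ± 4.58, 200.1 ± 163 and 119.8 ± 10.4 in the same order. In KDAC7 H709A its values in the 4 libraries were 422.2, 87.99, 68.5 and 221.8 CPM. It was higher in KDAC4 H803A than in KDAC4 H976Y (log2 fold change 1.54 ± 0.46, adjusted p = 0.0386; 0.00347 to 0.245 over the alternatives). It was also higher in KDAC7 H709A than in KDAC4 H976Y (log2 fold change 1.53 ± 0.43, adjusted p = 0.0344; 0.00571 to 0.096 over the alternatives). Both calls ended without any one of the KDAC4 H976Y libraries (adjusted p = 0.0578 to 0.0987 and 0.0587 to 0.096) or of the TMP195 libraries (0.0552 to 0.0567 and 0.0505 to 0.0516). The first also ended without KDAC4 H803A replicate 2 or 3 (adjusted p = 0.0862 and 0.0954), and the second without KDAC7 H709A replicate 1 or 4 (adjusted p = 0.0792 and 0.0676).

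Several measures set libraries apart. Mitochondrial ribosomal RNA took 16.1% to 31.5% of the counts in the 4 KDAC4 H976Y libraries and at most 0.345% in any other. Mitochondrially encoded mRNA took 0.676% to 1.41% there and 2.38% to 14.7% elsewhere, and small nucleolar RNA 0.722% to 0.913% there and at most 0.101% elsewhere. GC-rich genes exceeded GC-poor genes by 1.503 and 1.34 (log2) in KDAC4 H803A replicates 2 and 3 and by 1.25 in KDAC7 H709A replicate 1. The same difference was -1.20 in KDAC4 H803A replicate 1 and -0.48, -1.02 and -1.22 in KDAC7 H709A replicates 2, 3 and 4. The library labelled KDAC4 H803A replicate 1 and KDAC7 H709A replicate 4 had an overdispersion of 1.72 times Poisson counting, which is more than counting noise, and were kept as separate libraries. Against the other KDAC4 H803A libraries the same library had 149.2 and 156.9 times. Pairs within groups ran from 1.53 to 156.9, and the next lowest of 73 pairs between groups was 11.3, for KDAC7 H709A replicate 1 with KDAC4 H803A replicate 3. With its own group KDAC7 H709A replicate 1 had 81.5 to 128.7 times and KDAC7 H709A replicate 4 had 16.99 to 128.7 times. Each direction given for KDAC4 H803A rests in part on the library labelled replicate 1, and each for KDAC7 H709A in part on its replicates 1 and 4. Expressed genes of chromosome 13 had a median log2 difference of -0.79 between KDAC4 H976Y and the other groups (168 genes), those of chromosome 9 one of -0.32 (400 genes) and those of chromosome 6 one of -0.17 (508 genes).

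**Figure D1:**
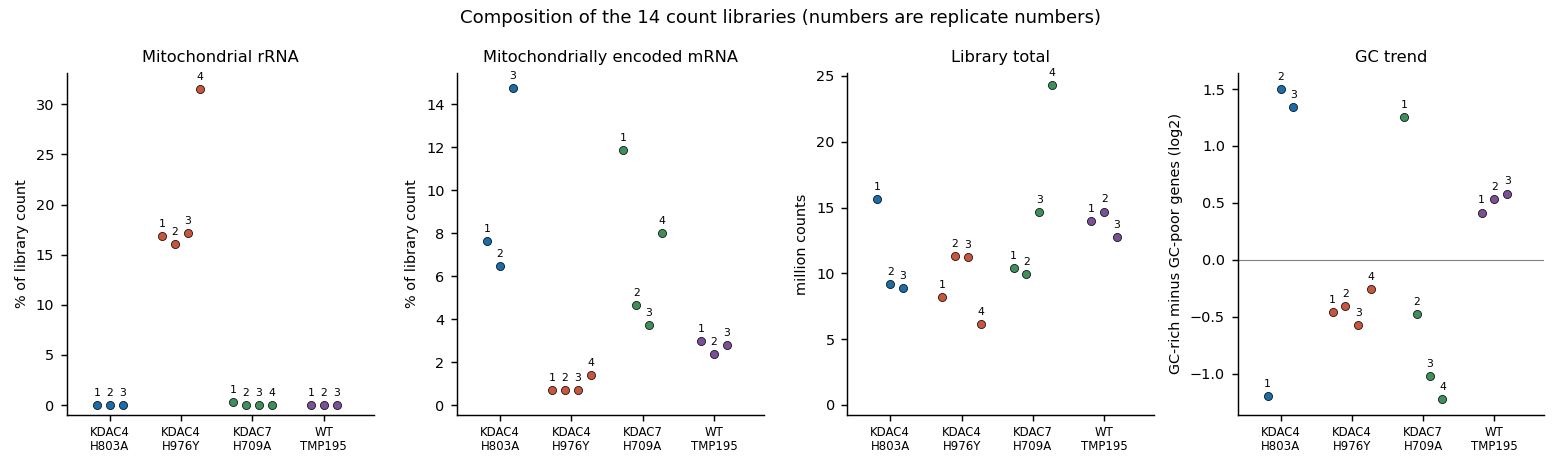
Share of counts from mitochondrial ribosomal RNA and from mitochondrially encoded mRNA (% of library count), total counts, and difference between GC-rich and GC-poor genes (log2), each point a library with its replicate number. The 4 KDAC4 H976Y libraries hold 16.1% to 31.5% mitochondrial ribosomal RNA, and KDAC4 H803A replicate 1 lies at -1.20 on the GC measure while replicates 2 and 3 lie at 1.503 and 1.34.

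**Figure D2:**
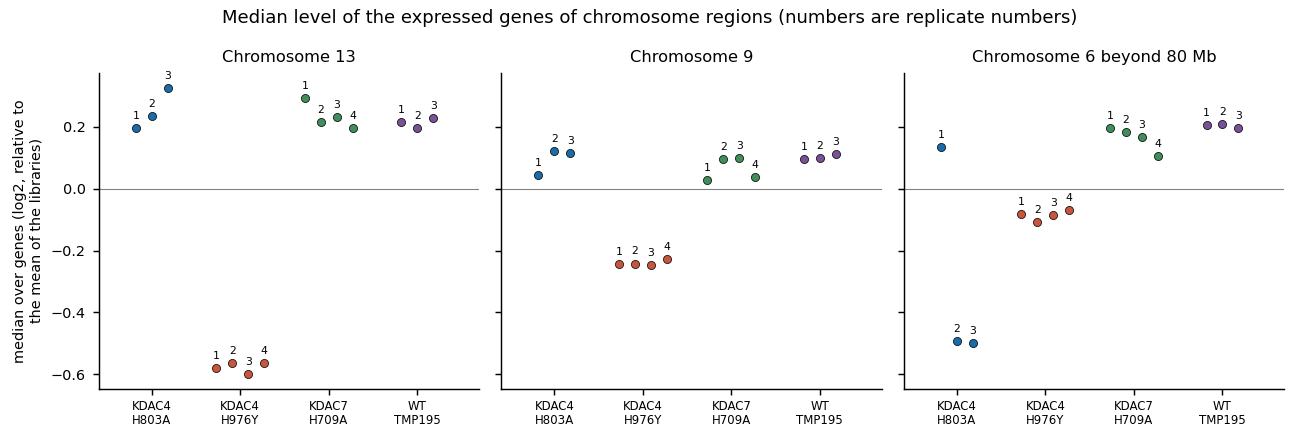
Median level of the expressed genes of chromosome 13, of chromosome 9 and of chromosome 6 beyond 80 Mb in each library (log2, relative to the mean of the libraries, after removal of GC and length trends), each point a library with its replicate number. KDAC4 H976Y lies lowest on chromosomes 13 and 9, and KDAC4 H803A replicates 2 and 3 lie at -0.49 and -0.50 on chromosome 6 beyond 80 Mb, where replicate 1 lies at 0.14.

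KDAC4 H803A against KDAC4 H976Y sets an inactive against an enhanced form of the same enzyme. Each KDAC4 H976Y library also stood apart from all others in its shares of mitochondrial ribosomal RNA, mitochondrially encoded mRNA and small nucleolar RNA. Genotype, preparation and chromosome-wide shifts cannot be told apart in the calls and list results of this comparison. The D-type cyclin CCND2 (ENSG00000118971, chromosome 12, 4273772 to 4305350) stood at 135 ± 24.9 CPM with inactive KDAC4 and 1.64 ± 0.763 CPM with the enhanced form (log2 fold change 6.29 ± 0.44, adjusted p = 9.77e-06). Neurofilament light chain NEFL (ENSG00000277586, chromosome 8, 24950955 to 24957110) stood at 29.6 ± 9.03 CPM against 0.194 ± 0.0357 CPM (log2 fold change 7.17 ± 0.58, adjusted p = 2.03e-05). The mesenchymal cadherin CDH11 (ENSG00000140937, chromosome 16, 64943753 to 65126112) was also higher (ratio 682-fold, with a counting interval of 189 to 5632, adjusted p = 0.000524), with 109.6, 13.4 and 10.8 CPM in the 3 KDAC4 H803A libraries and 2 counts in all of KDAC4 H976Y. In the other direction, the prostaglandin E synthase PTGES (ENSG00000148344, chromosome 9, 129738331 to 129753047) stood at 0.519 ± 0.383 CPM against 40.7 ± 8.89 CPM (log2 fold change -6.17 ± 0.45, adjusted p = 1.16e-05). The collagen-binding integrin subunit ITGA11 (ENSG00000137809, chromosome 15, 68296533 to 68432162) stood at 2.405 ± 0.311 CPM against 93.9 ± 3.55 CPM (log2 fold change -5.29 ± 0.54, adjusted p = 7.53e-05). Of 17780 genes tested 2679 were called, 1638 higher and 1041 lower with inactive KDAC4, 1972 of them by at least 2-fold.

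Of 21 immediate early genes 5 rose and 0 fell, or 12 and 0 adjusted over the list alone. Immediate early genes as a list had adjusted p = 5.36e-06, and adjusted p = 0.341 with an estimated correlation. EGR1, a transcription factor induced by serum, was higher (log2 fold change 4.51 ± 0.88, adjusted p = 0.00531). So were the phosphatase DUSP5 (log2 fold change 2.08 ± 0.20, adjusted p = 4.87e-05) and SPRY2 (log2 fold change 1.379 ± 0.25, adjusted p = 0.00362), an inhibitor of receptor signalling encoded on chromosome 13. Of 16 MEF2 factors and MEF2-regulated genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone. MEF2 genes as a list had adjusted p = 0.00927, and adjusted p = 0.296 with an estimated correlation. Their members KLF4 (log2 fold change 4.36 ± 0.54, adjusted p = 0.000384), on chromosome 9, and KLF6 (log2 fold change 1.15 ± 0.19, adjusted p = 0.00212) are zinc-finger regulators of growth and differentiation. Of 30 HOX genes, which set positional identity, 12 rose and 2 fell, or 13 and 2 adjusted over the list alone. HOX genes as a list had adjusted p = 0.00113, and adjusted p = 0.341 with an estimated correlation. HOXC8 (log2 fold change 2.45 ± 0.32, adjusted p = 0.000524) and HOXD9 (log2 fold change 2.77 ± 0.50, adjusted p = 0.00363) were among those that rose. HOXB13 rose too (log2 fold change 9.29 ± 1.84, adjusted p = 0.0059), with 3.17, 183.2 and 135.0 CPM in the 3 libraries. With GC and length offsets the MEF2 list did not pass (adjusted p = 0.0571; 0.0027 to 0.296 over the alternatives). With the offsets and the library labelled KDAC4 H803A replicate 1 left out, immediate early genes (adjusted p = 0.071; 7.55e-07 to 0.341 over the alternatives) and HOX genes (adjusted p = 0.168; 6.69e-05 to 0.341 over the alternatives) did not pass either.

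Matrix, adhesion and inflammatory lists had members called in both directions, and none of these lists passed. Of 30 collagens and matrix glycoproteins 4 rose and 9 fell, or 4 and 10 adjusted over the list alone. Their list adjusted p was 0.0997. The proteoglycan versican, VCAN, stood at 10.1 ± 3.71 CPM against 283 ± 50.3 CPM (log2 fold change -4.81 ± 0.83, adjusted p = 0.00282), and fibrillin FBN1 was lower as well (log2 fold change -2.57 ± 0.45, adjusted p = 0.00299). Integrins and cadherins had 1 higher and 5 lower of 24, or 3 and 5 adjusted over the list alone (adjusted p = 0.063), ITGB3 of the vitronectin receptor among the latter (log2 fold change -3.90 ± 0.48, adjusted p = 0.000385). TGF-beta and SMAD targets had 3 higher and 6 lower of 26, or 4 and 7 adjusted over the list alone (adjusted p = 0.524). The matricellular genes CYR61 (log2 fold change 2.44 ± 0.28, adjusted p = 0.000206) and CTGF (log2 fold change 2.43 ± 0.36, adjusted p = 0.00111) rose and TGFBI (log2 fold change -1.997 ± 0.43, adjusted p = 0.00967) fell. Inflammatory cytokines and NF-kB targets had 4 higher and 4 lower of 19, or 4 and 4 adjusted over the list alone (adjusted p = 0.925). The cytokine IL1B (log2 fold change -2.63 ± 0.35, adjusted p = 0.000631) and the inducible cyclooxygenase PTGS2 (log2 fold change -3.41 ± 0.55, adjusted p = 0.00186) were lower. TNFAIP3, a brake on NF-kB, was higher (log2 fold change 1.78 ± 0.33, adjusted p = 0.00375). Matrix proteases and inhibitors had 3 higher and 5 lower of 19, or 3 and 5 adjusted over the list alone (adjusted p = 0.405). The gelatinase MMP9 was higher (log2 fold change 5.43 ± 1.19, adjusted p = 0.0101), with 0.443, 23.2 and 14.2 CPM in the 3 libraries, the first within the range of KDAC4 H976Y.

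Of 29 hypoxia and glycolysis genes 1 rose and 9 fell, or 2 and 18 adjusted over the list alone. Hypoxia and glycolysis genes as a list had adjusted p = 2.48e-07, and adjusted p = 0.341 with an estimated correlation. Aldolase ALDOC (log2 fold change -3.39 ± 0.51, adjusted p = 0.0012) and the hypoxia-inducible factor EPAS1 (log2 fold change -1.75 ± 0.31, adjusted p = 0.00332) fell, and the carbonic anhydrase CA12 rose (log2 fold change 2.18 ± 0.39, adjusted p = 0.00333). Of 21 NRF2 targets 0 rose and 10 fell, or 0 and 13 adjusted over the list alone. NRF2 targets as a list had adjusted p = 8.49e-07, and adjusted p = 0.341 with an estimated correlation. They included GCLM of glutathione synthesis (log2 fold change -2.24 ± 0.46, adjusted p = 0.00678) and the aldo-keto reductase AKR1C1 (log2 fold change -3.11 ± 0.55, adjusted p = 0.00318), which shares reads with near-identical paralogs. Of 13 mitochondrially encoded mRNAs 12 rose and 0 fell, or 13 and 0 adjusted over the list alone. Mitochondrially encoded mRNAs as a list had adjusted p = 4.48e-16, and adjusted p = 0.296 with an estimated correlation. MT-ND6 stood at 2287 ± 887 CPM against 42.5 ± 30.7 CPM (log2 fold change 5.76 ± 0.58, adjusted p = 7.53e-05). Mitochondrial ribosomal RNA moved the opposite way, at no more than 0.0256% against at least 16.1% of counts. Of 43 cytosolic ribosomal proteins 1 rose and 7 fell, or 1 and 7 adjusted over the list alone. Ribosomal proteins as a list had adjusted p = 9.46e-05, and adjusted p = 0.6 with an estimated correlation. RPS12 was among those that fell (log2 fold change -2.22 ± 0.36, adjusted p = 0.00203). Of 29 replication-dependent histones, whose near-identical copies share reads, 1 rose and 9 fell, or 1 and 11 adjusted over the list alone. Histones as a list had adjusted p = 0.00318, and adjusted p = 0.548 with an estimated correlation. HIST1H2BK was among those that fell (log2 fold change -1.79 ± 0.27, adjusted p = 0.0012).

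The remaining lists did not pass in this comparison. Lysine deacetylases and corepressor subunits had 7 higher and 0 lower of 26, or 8 and 1 adjusted over the list alone (adjusted p = 0.0678). Interferon-stimulated genes had 2 higher and 3 lower of 29, or 2 and 6 adjusted over the list alone (adjusted p = 0.063), OAS3 among the former (log2 fold change 1.77 ± 0.29, adjusted p = 0.00215). Chondro-osteogenic genes had 3 higher and 1 lower of 10, or 3 and 2 adjusted over the list alone (adjusted p = 0.604), the cartilage regulator SOX9 among the former (log2 fold change 1.20 ± 0.21, adjusted p = 0.00329). Myogenic and contractile genes had 1 higher and 0 lower of 11, or 3 and 0 adjusted over the list alone (adjusted p = 0.285). Cell cycle genes had 3 higher and 0 lower of 32, or 2 and 0 adjusted over the list alone (adjusted p = 0.746). Cholesterol synthesis genes had 1 higher and 0 lower of 23, or 1 and 0 adjusted over the list alone (adjusted p = 0.677). p53 targets had 1 higher and 1 lower of 24, or 0 and 0 adjusted over the list alone (adjusted p = 0.598). Amino acid and unfolded protein response genes had 1 higher and 2 lower of 27, or 2 and 4 adjusted over the list alone (adjusted p = 0.598). Markers of other cell types were 1 higher of 7 epithelial (adjusted p = 0.405), 1 of 7 endothelial (adjusted p = 0.347) and 1 of 3 blood markers (adjusted p = 0.604). Neural markers had 2 higher and 1 lower of 8 (adjusted p = 0.276). The blood marker was LCP1, on chromosome 13 (log2 fold change 1.67 ± 0.34, adjusted p = 0.00636). The list median was above 0 and the test lower for proteases (0.33), p53 targets (0.06), NF-kB targets (0.44) and the amino acid response (0.01). The median was below 0 and the test higher for chondro-osteogenic genes (-0.08), and the mean above 0 and the test lower for integrins (0.06) and the cell cycle (0.04).

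Sides did not overlap in 2323 of the 2679 calls and in 23.1% of all tested genes, where chance gives 5.71%. The count was 8431 without the library labelled KDAC4 H803A replicate 1, 2583 of them among the 2679, and the share of calls that were higher fell from 61.1% to 49.4%. It was 1262 and 1129 without KDAC4 H803A replicates 2 and 3, 1310, 1246 and 1269 without KDAC4 H976Y replicates 1, 2 and 3, and 4667 without KDAC7 H709A replicate 1.

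KDAC7 H709A against KDAC4 H976Y sets inactive KDAC7 against enhanced KDAC4. Here too genotype, preparation and chromosome-wide shifts of KDAC4 H976Y cannot be told apart. CCND2 stood at 128 ± 55.3 CPM against 1.64 ± 0.763 CPM (log2 fold change 6.21 ± 0.43, adjusted p = 6.49e-06). NEFL (log2 fold change 6.81 ± 0.56, adjusted p = 1.47e-05), KLF4 (log2 fold change 4.89 ± 0.52, adjusted p = 0.000111) and the class IIa deacetylase gene HDAC9 (log2 fold change 1.68 ± 0.29, adjusted p = 0.00236) were also higher. The copper ferroxidase HEPH (ENSG00000089472, chromosome X, 66162549 to 66268867) was lower (ratio 568-fold, with a counting interval of 102 to 22420.0, adjusted p = 0.000162). The guanine nucleotide exchange factor DOCK8, on chromosome 9, was lower (ratio 231-fold, with a counting interval of 64.0 to 1910.0, adjusted p = 0.000545). The fibrillar collagen chain COL1A2 had 0 counts against 2.81 ± 0.246 CPM, at least 57.7-fold lower (adjusted p = 0.000129). The tubulin gene TUBA3C, which shares reads with near-identical paralogs and lies on chromosome 13, stood at 43.0 ± 9.89 CPM against 0 counts, at least 439-fold higher (adjusted p = 9.66e-06). Of 17780 genes 2218 were called, 1295 higher and 923 lower with inactive KDAC7, 1538 of them by at least 2-fold.

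Of 21 immediate early genes 6 rose and 0 fell, or 10 and 0 adjusted over the list alone. Immediate early genes as a list had adjusted p = 0.000108, and adjusted p = 0.361 with an estimated correlation. EGR1 (log2 fold change 4.96 ± 0.87, adjusted p = 0.00259), DUSP5 (log2 fold change 2.32 ± 0.19, adjusted p = 1.47e-05) and SPRY4 (log2 fold change 1.35 ± 0.21, adjusted p = 0.00149) were among those that rose. Of 16 MEF2 factors and MEF2-regulated genes 6 rose and 0 fell, or 6 and 0 adjusted over the list alone. MEF2 genes as a list had adjusted p = 0.00294, and adjusted p = 0.238 with an estimated correlation. Of 30 HOX genes 10 rose and 1 fell, or 14 and 2 adjusted over the list alone. HOX genes as a list had adjusted p = 0.00369, and adjusted p = 0.361 with an estimated correlation. HOXC8 (log2 fold change 2.53 ± 0.30, adjusted p = 0.000242) and HOXB2 (log2 fold change 1.83 ± 0.29, adjusted p = 0.00147) were among those that rose. Of 23 cholesterol synthesis genes and SREBP2 targets 6 rose and 0 fell, or 9 and 0 adjusted over the list alone. Cholesterol synthesis genes as a list had adjusted p = 0.000227, and adjusted p = 0.361 with an estimated correlation. They included SREBF2, the factor that induces the pathway (log2 fold change 1.13 ± 0.16, adjusted p = 0.000634), and lanosterol synthase LSS (log2 fold change 1.07 ± 0.18, adjusted p = 0.00203).

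Of 30 collagens and matrix glycoproteins 4 rose and 8 fell, or 5 and 9 adjusted over the list alone. Collagens and matrix glycoproteins as a list had adjusted p = 0.0325, and adjusted p = 0.361 with an estimated correlation. That call ended without KDAC7 H709A replicate 3 (adjusted p = 0.0933; 0.0044 to 0.361 over the alternatives). VCAN was lower (log2 fold change -3.77 ± 0.70, adjusted p = 0.0036) and tenascin TNC, on chromosome 9, higher (log2 fold change 2.04 ± 0.19, adjusted p = 3.19e-05). Of 29 hypoxia and glycolysis genes 1 rose and 7 fell, or 1 and 8 adjusted over the list alone. Hypoxia and glycolysis genes as a list had adjusted p = 2.14e-05, and adjusted p = 0.361 with an estimated correlation. ALDOC (log2 fold change -2.46 ± 0.42, adjusted p = 0.00242) and the glycolytic regulator PFKFB4 (log2 fold change -1.64 ± 0.32, adjusted p = 0.00512) fell and CA12 rose (log2 fold change 2.92 ± 0.38, adjusted p = 0.000417). Of 21 NRF2 targets 0 rose and 5 fell, or 0 and 9 adjusted over the list alone. NRF2 targets as a list had adjusted p = 4.31e-05, and adjusted p = 0.361 with an estimated correlation. Of 13 mitochondrially encoded mRNAs 12 rose and 0 fell, or 12 and 0 adjusted over the list alone. Mitochondrially encoded mRNAs as a list had adjusted p = 2.11e-15, and adjusted p = 0.327 with an estimated correlation. MT-ND6 was among them (log2 fold change 5.43 ± 0.57, adjusted p = 9.42e-05), beside mitochondrial ribosomal RNA of at most 0.345% against at least 16.1% of counts. Of 43 cytosolic ribosomal proteins 1 rose and 9 fell, or 1 and 10 adjusted over the list alone. Ribosomal proteins as a list had adjusted p = 1.51e-05, and adjusted p = 0.543 with an estimated correlation. RPL37 was among those that fell (log2 fold change -1.61 ± 0.35, adjusted p = 0.0089). Of 29 replication-dependent histones 1 rose and 7 fell, or 1 and 8 adjusted over the list alone. Histones as a list had adjusted p = 0.00707, and adjusted p = 0.543 with an estimated correlation. The histone call ended with GC and length offsets (adjusted p = 0.405; 0.00061 to 0.543 over the alternatives).

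The other lists did not pass. TGF-beta and SMAD targets had 2 higher and 4 lower of 26, or 2 and 4 adjusted over the list alone (adjusted p = 0.578). CTGF was higher (log2 fold change 2.85 ± 0.35, adjusted p = 0.00027) and the activin subunit INHBA lower (log2 fold change -2.45 ± 0.37, adjusted p = 0.00118). Inflammatory cytokines and NF-kB targets had 5 higher and 4 lower of 19, or 5 and 4 adjusted over the list alone (adjusted p = 0.578). PTGS2 (log2 fold change -3.73 ± 0.49, adjusted p = 0.000488) and IL1A (log2 fold change -2.87 ± 0.47, adjusted p = 0.00171) were lower. Interferon-stimulated genes had 3 higher and 3 lower of 29, or 3 and 7 adjusted over the list alone (adjusted p = 0.32). OAS3 was higher (log2 fold change 2.37 ± 0.28, adjusted p = 0.000236) and IFI27 lower (log2 fold change -3.37 ± 0.62, adjusted p = 0.00354). Integrins and cadherins had 2 higher and 3 lower of 24, or 3 and 4 adjusted over the list alone (adjusted p = 0.421), ITGA11 among the latter (log2 fold change -3.58 ± 0.43, adjusted p = 0.000236). Matrix proteases and inhibitors had 1 higher and 1 lower of 19, or 1 and 2 adjusted over the list alone (adjusted p = 0.578), MMP14 being the lower (log2 fold change -1.02 ± 0.17, adjusted p = 0.0022). Chondro-osteogenic genes had 2 higher and 1 lower of 10, or 3 and 1 adjusted over the list alone (adjusted p = 0.32), BMP2 being the lower (log2 fold change -2.14 ± 0.32, adjusted p = 0.000966). Lysine deacetylases and corepressor subunits had 3 higher and 0 lower of 26, or 3 and 0 adjusted over the list alone (adjusted p = 0.142). Myogenic and contractile genes had 1 higher and 0 lower of 11, or 2 and 0 adjusted over the list alone (adjusted p = 0.982). Cell cycle genes had 3 higher and 0 lower of 32, or 1 and 0 adjusted over the list alone (adjusted p = 0.578). p53 targets had 0 higher and 1 lower of 24, or 0 and 0 adjusted over the list alone (adjusted p = 0.135). Amino acid and unfolded protein response genes had 0 higher and 0 lower of 27, or 0 and 0 adjusted over the list alone (adjusted p = 0.527). Neural markers had 3 higher and 1 lower of 8, or 5 and 1 adjusted over the list alone (adjusted p = 0.138). Of the other markers, 1 epithelial was lower (adjusted p = 0.955), 1 endothelial higher (adjusted p = 0.314) and 1 blood marker higher (adjusted p = 0.982). The list median was above 0 and the test lower for proteases (0.31), integrins (0.02), TGF-beta targets (0.03), interferon-stimulated genes (0.01), NF-kB targets (0.40) and epithelial markers (0.07). It was below 0 and the test higher for the cell cycle (-0.08) and blood markers (-0.47).

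Sides did not overlap in 2042 of the 2218 calls and in 20.1% of all tested genes, where chance gives 2.86%. The count was 3440 without the library labelled KDAC4 H803A replicate 1, which shares the estimate of the spread, and 1242, 1215 and 1221 without KDAC4 H976Y replicates 1, 2 and 3.

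**Figure D3:**
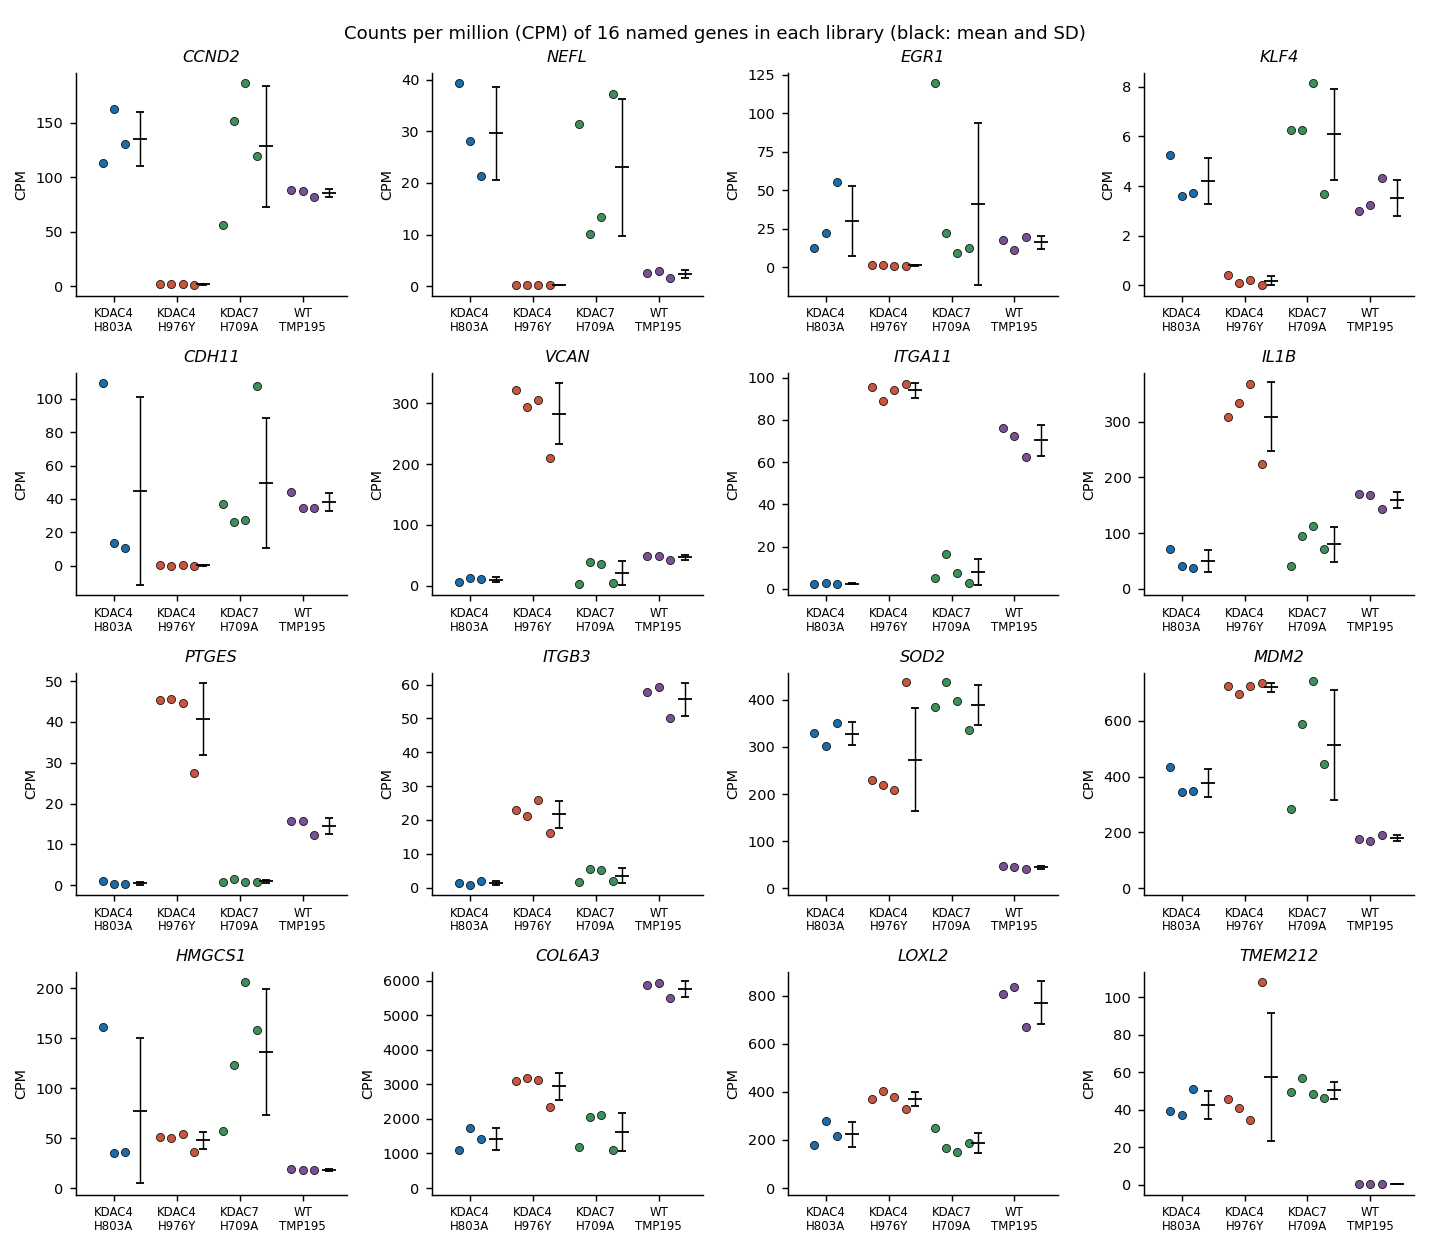
CPM of 16 named genes in each library, a point per library and panel per gene, with the mean and SD of each group in black. CCND2 has mean ± SD of 1.64 ± 0.763 CPM in KDAC4 H976Y against 135 ± 24.9 CPM in KDAC4 H803A, and SOD2 of 45.1 ± 2.96 CPM in TMP195-treated cells against 389 ± 42.0 CPM in KDAC7 H709A.

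KDAC7 H709A against KDAC4 H803A sets the inactive forms of both enzymes against each other. With edgeR 0 of 17780 genes were called, 1118 had an unadjusted p under 0.05, where chance alone gives 889, and the DESeq2 Wald test called 79. HMGCS1, which makes the precursor of mevalonate, stood at 136 ± 62.7 CPM with inactive KDAC7 and 77.5 ± 72.8 CPM with inactive KDAC4 (adjusted p = 0.634). MMP9 stood at 0.878 ± 0.538 CPM and 12.7 ± 11.5 CPM (adjusted p = 0.545). Although no gene was called, 5 lists passed. Cholesterol synthesis genes and SREBP2 targets were tested higher with inactive KDAC7 (median 0.47, adjusted p = 5.5e-06), as were hypoxia and glycolysis genes (median 0.33, adjusted p = 0.0135). NRF2 targets (median 0.38, adjusted p = 0.0135) and integrins and cadherins (median 0.47, adjusted p = 0.0168) were tested higher too. Mitochondrially encoded mRNAs were tested lower (median -0.37, adjusted p = 0.0135). With an estimated correlation each of the 5 had adjusted p = 0.842. Adjusted over the list alone, 2 matrix proteases and inhibitors and 1 p53 target were lower, and 0 genes of the other lists passed.

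The cholesterol list passed with each library left out. NRF2 targets did not pass without the library labelled KDAC4 H803A replicate 1 (adjusted p = 0.0503; 0.00142 to 0.842 over the alternatives). Hypoxia genes and integrins did not pass without KDAC4 H803A replicate 3 (adjusted p = 0.162 each; 0.000208 to 0.842 and 0.000519 to 0.842 over the alternatives). Mitochondrially encoded mRNAs did not pass without KDAC4 H803A replicates 1 or 3 or KDAC7 H709A replicates 2 or 3 (adjusted p = 0.352, 0.398, 0.153 and 0.324; 4.48e-08 to 0.842 over the alternatives). The other lists did not pass. Their adjusted p was 0.56 for lysine deacetylases, 0.969 for MEF2, 0.0991 for myogenic, 0.656 for chondro-osteogenic genes, 0.973 for collagens, 0.613 for proteases and 0.877 for TGF-beta targets. It was 0.261 for the cell cycle, 0.286 for p53 targets, 0.122 for interferon-stimulated genes, 0.801 for NF-kB targets, 0.272 for immediate early genes and 0.973 for the amino acid response. It was 0.261 for HOX genes, 0.996 for ribosomal proteins, 0.56 for histones, and 0.0938, 0.973, 0.594 and 0.968 for epithelial, endothelial, blood and neural markers. The median was below 0 and the test higher for MEF2 (-0.05) and the amino acid response (-0.03), and the mean was for proteases (-0.21). The median was above 0 and the test lower for HOX genes (0.02), ribosomal proteins (0.09) and immediate early genes (0.002), and the mean was for endothelial markers (0.15).

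Sides did not overlap in 2.01% of tested genes, where chance gives 5.71%. The count of 0 was 4788 without the library labelled KDAC4 H803A replicate 1, whose counts lay nearest to those of KDAC7 H709A replicate 4.

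The fold changes of both inactive forms against the shared KDAC4 H976Y libraries correlated across 17780 genes at r = 0.791 (covariance 0.848). Unchanged groups simulated against the same libraries gave 0.196 (0.167 to 0.228; covariance 0.057), a difference in covariance of 0.791. Splitting the KDAC4 H976Y libraries between the comparisons gave 0.691 to 0.716. Overdispersion was 1.72 between KDAC4 H803A replicate 1 and KDAC7 H709A replicate 4, and 11.3 between their replicates 3 and 1. The sides are not independent as the simulation and independent lists assume. Without the first library r was 0.586, with the 11.3 pair kept. Of the 1638 genes called higher in KDAC4 H803A 59.6% were also called higher in KDAC7 H709A (7.28% for independent lists), and of the 1041 lower 59.1% (5.19%), or 615 genes. Against the same libraries TMP195-treated cells correlated with KDAC4 H803A at 0.651 (covariance 0.852, simulated r 0.304, 0.269 to 0.331, covariance difference 0.794), or 0.575 to 0.594 with split libraries. With KDAC7 H709A they correlated at 0.626 (covariance 0.692, simulated r 0.398, 0.374 to 0.435, covariance difference 0.634), or 0.534 to 0.558 with split libraries. They shared 776 higher and 395 lower calls with KDAC4 H803A (130.5 and 89.0 for independent lists) and 707 and 377 with KDAC7 H709A (103.1 and 78.9). Genes are not independent replicates. Mitochondrial ribosomal RNA of at least 16.1% and a chromosome 13 median of -0.79 set KDAC4 H976Y apart from each other group.

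TMP195 against the variants sets inhibitor-treated wild-type cells against the mean of the 3 untreated variant groups, so that genotype and treatment change together. The collagen chain COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375) stood at 5761 ± 238 CPM against 1415 ± 312, 2939 ± 404 and 1622 ± 546 in KDAC4 H803A, KDAC4 H976Y and KDAC7 H709A (log2 fold change 1.61 ± 0.21, adjusted p = 0.000326). The lysyl oxidase LOXL2 (log2 fold change 1.63 ± 0.16, adjusted p = 4.1e-05) was higher too. The procollagen protease ADAMTS2 stood at 9.78 ± 1.02 CPM, with 1 count in all variant libraries (ratio 1248-fold, with a counting interval of 224 to 49280.0, adjusted p = 8.29e-05). Mitochondrial superoxide dismutase SOD2 (ENSG00000112096, chromosome 6, 159669057 to 159745186) was lower, at 45.1 ± 2.96 CPM against 328 ± 24.9, 273 ± 109 and 389 ± 42.0 (log2 fold change -2.86 ± 0.25, adjusted p = 1.38e-05). MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686), a ubiquitin ligase that p53 induces and that degrades it, stood at 179 ± 11.01 CPM against 376 ± 49.8, 719 ± 16.3 and 515 ± 197 (log2 fold change -1.53 ± 0.24, adjusted p = 0.00151). Of 17780 genes 1640 were called, 708 higher and 932 lower, 1167 of them by at least 2-fold.

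Of 23 cholesterol synthesis genes and SREBP2 targets 0 rose and 10 fell, or 0 and 18 adjusted over the list alone. Cholesterol synthesis genes as a list had adjusted p = 3.35e-09, and adjusted p = 0.258 with an estimated correlation. HMGCS1 stood at 18.2 ± 0.922 CPM (log2 fold change -2.13 ± 0.50, adjusted p = 0.0171), with the isomerase IDI1 (log2 fold change -2.02 ± 0.45, adjusted p = 0.0135) and the sterol oxidase MSMO1 (log2 fold change -2.02 ± 0.52, adjusted p = 0.0272) also lower. These 3 genes did not pass without TMP195 replicate 1 (adjusted p = 0.0894, 0.0668 and 0.128), replicate 2 (0.0994, 0.0948 and 0.117) or replicate 3 (0.0978, 0.0776 and 0.138), while the list passed each time. Of 24 p53 targets 1 rose and 8 fell, or 2 and 12 adjusted over the list alone. p53 targets as a list had adjusted p = 5.88e-05, and adjusted p = 0.249 with an estimated correlation. The antiproliferative gene BTG2 was among those that fell (log2 fold change -1.51 ± 0.26, adjusted p = 0.00267). Of 29 interferon-stimulated genes 0 rose and 7 fell, or 0 and 8 adjusted over the list alone. Interferon-stimulated genes as a list had adjusted p = 5.88e-05, and adjusted p = 0.338 with an estimated correlation. The histocompatibility gene HLA-C, which shares reads with near-identical copies, fell (log2 fold change -6.32 ± 0.43, adjusted p = 2.47e-06).

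Of 27 amino acid and unfolded protein response genes 8 rose and 0 fell, or 8 and 0 adjusted over the list alone. Amino acid and unfolded protein response genes as a list had adjusted p = 0.000272, and adjusted p = 0.425 with an estimated correlation. The glutathione-degrading enzyme CHAC1 (log2 fold change 1.25 ± 0.23, adjusted p = 0.00453) and the amino acid transporter subunit SLC7A5 (log2 fold change 1.12 ± 0.18, adjusted p = 0.00165) rose, the latter with adjusted p = 0.0527 under GC and length offsets (9.68e-08 to 0.0527 over the alternatives). Of 29 hypoxia and glycolysis genes 3 rose and 0 fell, or 3 and 0 adjusted over the list alone. Hypoxia and glycolysis genes as a list had adjusted p = 0.00538, and adjusted p = 0.624 with an estimated correlation. Of 29 replication-dependent histones 6 rose and 0 fell, or 16 and 1 adjusted over the list alone. Histones as a list had adjusted p = 7.29e-05, and adjusted p = 0.511 with an estimated correlation. HIST1H3H was among those that rose (log2 fold change 1.12 ± 0.18, adjusted p = 0.00208). The histone list did not pass with GC and length offsets (adjusted p = 0.235; 1.21e-06 to 0.511 over the alternatives). Of 13 mitochondrially encoded mRNAs 0 rose and 1 fell, or 0 and 5 adjusted over the list alone. Mitochondrially encoded mRNAs as a list had adjusted p = 0.000413, and adjusted p = 0.624 with an estimated correlation. Their share of counts was 2.38% to 2.98% in treated cells, above 0.676% to 1.41% in KDAC4 H976Y and below at least 3.72% in the other libraries.

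Further lists did not pass. Collagens and matrix glycoproteins had 5 higher and 1 lower of 30, or 5 and 1 adjusted over the list alone (adjusted p = 0.0739), the collagen chain COL8A1 being the lower (log2 fold change -1.56 ± 0.27, adjusted p = 0.00286). Matrix proteases and inhibitors had 3 higher and 0 lower of 19, or 3 and 0 adjusted over the list alone (adjusted p = 0.139). Integrins and cadherins had 5 higher and 1 lower of 24, or 6 and 1 adjusted over the list alone (adjusted p = 0.191), ITGB8 being the lower (log2 fold change -3.81 ± 0.48, adjusted p = 0.000278). ITGB3 stood at 55.7 ± 4.93 CPM (log2 fold change 3.53 ± 0.30, adjusted p = 1.15e-05), and did not pass in a fit of the 2 sides as the only groups (adjusted p = 0.0807; 6.65e-22 to 0.0807 over the alternatives). TGF-beta and SMAD targets had 6 higher and 0 lower of 26, or 6 and 0 adjusted over the list alone (adjusted p = 0.235). NRF2 targets had 2 higher and 0 lower of 21, or 3 and 0 adjusted over the list alone (adjusted p = 0.1), heme oxygenase HMOX1 among the former (log2 fold change 1.82 ± 0.20, adjusted p = 0.000105). Cell cycle genes had 3 higher and 0 lower of 32, or 3 and 0 adjusted over the list alone (adjusted p = 0.235). Myogenic and contractile genes had 2 higher and 0 lower of 11, or 3 and 2 adjusted over the list alone (adjusted p = 0.733). Lysine deacetylases and corepressor subunits had 1 higher and 0 lower of 26, or 0 and 0 adjusted over the list alone (adjusted p = 0.942). Immediate early genes had 1 higher and 0 lower of 21, or 1 and 0 adjusted over the list alone (adjusted p = 0.574). MEF2 genes had 0 higher and 1 lower of 16, or 0 and 1 adjusted over the list alone (adjusted p = 0.931). Chondro-osteogenic genes had 0 higher and 1 lower of 10, or 0 and 1 adjusted over the list alone (adjusted p = 0.931). HOX genes had 0 higher and 1 lower of 30, or 0 and 0 adjusted over the list alone (adjusted p = 0.0845). Inflammatory cytokines and NF-kB targets had 2 higher and 2 lower of 19, or 2 and 2 adjusted over the list alone (adjusted p = 0.733). Ribosomal proteins had 3 higher and 1 lower of 43, or 3 and 1 adjusted over the list alone (adjusted p = 0.495). Epithelial and neural markers had 0 calls (adjusted p = 0.139 and 0.574), and endothelial and blood markers 1 lower each (adjusted p = 0.931 and 0.842). The list median was above 0 and the test lower for MEF2 (0.09), chondro-osteogenic genes (0.02) and blood markers (0.24), and the mean was for deacetylases (0.06). The median was below 0 and the test higher for integrins (-0.01) and immediate early genes (-0.05), and the mean was for NF-kB targets (-0.24).

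Sides did not overlap in 1194 of the 1640 calls and in 9.09% of tested genes, where chance gives 0.549%. The count was 584, 597 and 611 without TMP195 replicates 1, 2 and 3 and 2761 without KDAC7 H709A replicate 1.

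**Figure D4:**
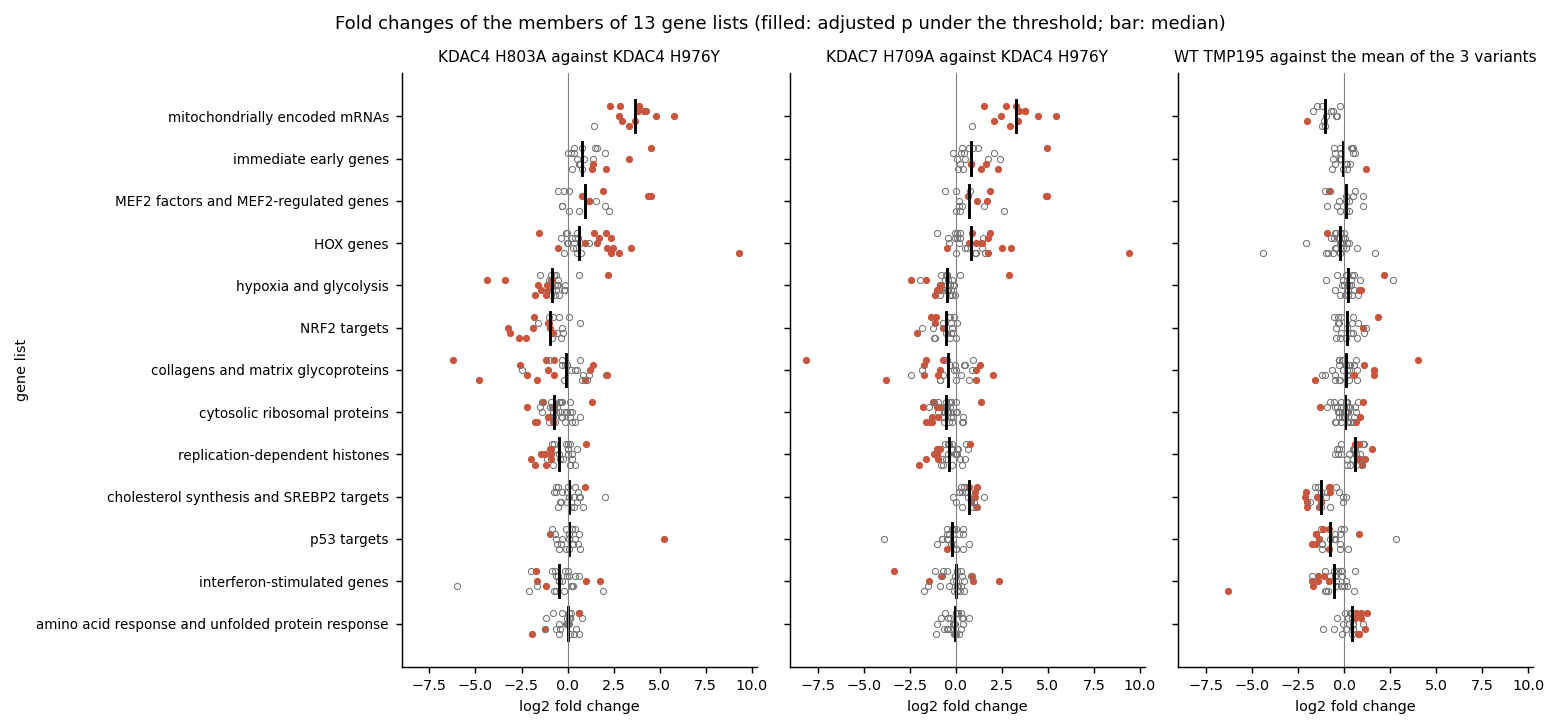
Log2 fold changes of the members of 13 gene lists in 3 comparisons, a point per gene, filled where the adjusted p passed the threshold, with a bar at the list median. Mitochondrially encoded mRNAs lie to the right of 0 in both comparisons against KDAC4 H976Y (medians 3.64 and 3.25), and cholesterol synthesis genes to the left in TMP195-treated cells (median -1.23).

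Against single variants, TMP195-treated cells had 949 calls against KDAC4 H803A (277 higher, 672 lower), 2936 against KDAC4 H976Y (1416 higher, 1520 lower) and 1119 against KDAC7 H709A (353 higher, 766 lower). Of these 811, 2214 and 889 were of at least 2-fold. In the calls against KDAC4 H976Y, genotype, treatment, preparation and chromosome-wide shifts cannot be told apart. Non-overlapping sides were found in 936, 2923 and 1112 of the calls and in 24.3%, 53.8% and 24.3% of tested genes, where chance gives 10.0%, 5.71% and 5.71%. Without the library labelled KDAC4 H803A replicate 1 the counts were 2695, 5079 and 2708, and without KDAC7 H709A replicate 1 they were 1438, 4451 and 2755. Without TMP195 replicates 1, 2 and 3 they were 446, 436 and 476 against KDAC4 H803A, 1386, 1358 and 1307 against KDAC4 H976Y, and 437, 422 and 451 against KDAC7 H709A. The count against KDAC4 H803A was 562 without its replicate 3, that against KDAC4 H976Y 1729, 1722 and 1708 without its replicates 1, 2 and 3, and that against KDAC7 H709A 724 without its replicate 2.

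Genes set apart from all 3 other groups in one direction numbered 900 for KDAC4 H976Y (290 higher, 610 lower) and 473 for TMP195 (60 higher, 413 lower). In those of KDAC4 H976Y genotype, preparation and chromosome-wide shifts cannot be told apart. Of its lower genes 65 lie on chromosome 13 and 54 on chromosome 9. The edgeR test set apart 0 genes for KDAC4 H803A and 0 for KDAC7 H709A, and DESeq2 21 and 26, while 1118 genes had an unadjusted p under 0.05 between these groups, where chance alone gives 889. KDAC4 H976Y stood alone in the endothelial lipase LIPG (ENSG00000101670, chromosome 18, 49560699 to 49599182), at 52.3 ± 6.99 CPM against 2.20 ± 0.0930, 2.92 ± 1.69 and 1.85 ± 0.234 in KDAC4 H803A, KDAC7 H709A and TMP195. MTRNR2L1, a nuclear copy of MT-RNR2 that shares its reads, stood at 6844 ± 2977 CPM there, against at most 5.11 ± 10.2 CPM in the other groups. Treated cells stood alone in TMEM212 (ENSG00000186329, chromosome 3, 171843349 to 171938715), at 0.169 ± 0.0309 CPM against 42.5 ± 7.24, 57.3 ± 34.1 and 50.3 ± 4.62 in KDAC4 H803A, KDAC4 H976Y and KDAC7 H709A (log2 fold change -8.11 ± 0.50, adjusted p = 2.34e-06 against their mean). They also stood alone in the tyrosine kinase FRK (log2 fold change -7.56 ± 0.58, adjusted p = 5.94e-06). Without the library labelled KDAC4 H803A replicate 1 the counts were 995 for KDAC4 H803A, 255 for KDAC7 H709A, 1348 for KDAC4 H976Y and 631 for TMP195. The count for KDAC4 H976Y was 461, 459 and 442 without its replicates 1, 2 and 3 and 496, 486 and 493 without TMP195 replicates 1, 2 and 3. The count for TMP195 was 250.0, 243 and 259 without its replicates 1, 2 and 3.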

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

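The tests of mitochondrial ribosomal RNA given here were chosen after the values were seen, and the counts over other splits of the libraries were planned before. In the groups of 4 libraries a value was singled out where its gap to the nearest of the others passed the critical value of Dixon's test for 4 values. Of 166 groups of values tested 26 were singled out, where chance alone singles out about 5%, and genes of 1 library do not vary independently. KDAC4 H976Y replicate 4 stood apart with 31.5% mitochondrial ribosomal RNA (16.1% to 17.2% in the others), 1.41% mitochondrially encoded mRNA (0.676% to 0.701%) and 52.6% nuclear protein-coding counts (69.0% to 70.4%). KDAC7 H709A replicate 1 stood apart with 0.345% mitochondrial ribosomal RNA (0.0003% to 0.0008% in the others) and 8.69% 7SL, 7SK and other small structural RNAs (1.93% to 2.62%).

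In KDAC4 H976Y replicate 4 these named genes stood apart, with the range of the other 3 libraries in parentheses. MT-ND6 had 88.4 CPM (25.2 to 29.7), MTRNR2L1, which shares reads with MT-RNR2, 11300.0 CPM (5183 to 5540.0), SOD2 436.9 CPM (208.8 to 228.8), TMEM212 107.9 CPM (34.6 to 45.9), FRK 39.5 CPM (13.6 to 16.3) and HDAC4 21.8 CPM (15.2 to 15.9). COL6A3 had 2334 CPM (3110.0 to 3189), MMP14 1227 CPM (1595 to 1626), LIPG 41.8 CPM (55.2 to 56.6), PTGES 27.4 CPM (44.6 to 45.5) and IFI27 2.06 CPM (3.94 to 4.22). In KDAC4 H976Y replicate 1 HOXD9 had 1.27 CPM (1.95 to 2.06) and NEFL 0.141 CPM (0.206 to 0.216). In KDAC7 H709A replicate 1 HOXB13 had 392.1 CPM (4.03 to 33.8), EGR1 119.5 CPM (9.08 to 22.4), MTRNR2L1 20.4 CPM (0 to 0.0839), DOCK8 0.193 CPM (0 in the others) and EPAS1 59.1 CPM (100.4 to 104.7). In KDAC7 H709A replicate 2 PTGES had 1.56 CPM (0.772 to 0.876) and HEPH 0.0868 CPM (0 in the others), and in replicate 4 CDH11 had 107.6 CPM (25.9 to 37.1).

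Mitochondrial ribosomal RNA of at least 16.1% in the 4 KDAC4 H976Y libraries was weighed against 2 explanations. More mitochondrial transcripts of every kind would raise mitochondrially encoded mRNA too, and the tables argue against that: its highest share in KDAC4 H976Y was 1.41%, under the lowest of the other groups, 2.38%. A less complete depletion of ribosomal RNA, or another preparation of these libraries, may underlie the pattern; no other group passed 0.345%, so preparation and genotype cannot be told apart, because no KDAC4 H976Y library is stated to have been prepared in another way. An effect of the variant on mitochondrial ribosomal RNA itself stays open and untested.

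Other splits of the same libraries into groups of the same sizes were counted for each result of a fit across genes. For KDAC7 H709A against KDAC4 H976Y 1 of 35 splits, the real one, called 2218 genes or more and the highest other called 0, and for TMP195 against KDAC4 H976Y it was 1 of 35 (2936, highest other 181). For TMP195 against the variants it was 1 of 100 drawn (1640, highest other 1438), and for genes set apart in KDAC4 H976Y and in TMP195 1 of 100 each (900 and 473, highest other 0 in both). Under 0.05 of the splits reached these counts, so a random grouping of these libraries seldom gives as many. The splits cannot tell an effect of genotype or treatment from any other trait shared by a group's libraries, such as preparation or clone. For KDAC4 H803A against KDAC4 H976Y 2 of 35 splits called as many (2679, highest other 5350) and for TMP195 against KDAC7 H709A 2 of 35 (1119, highest other 2637), so chance was not excluded. The first of these highest other splits sets KDAC4 H803A replicates 2 and 3 with KDAC4 H976Y replicate 4 against the rest, and the second sets KDAC7 H709A replicates 2, 3 and 4 against the TMP195 libraries with KDAC7 H709A replicate 1. For KDAC7 H709A against KDAC4 H803A all 35 splits called at least the real 0 of edgeR's test, as any split must (1118 genes at an unadjusted p under 0.05, where chance gives 889, and 79 called by DESeq2). The highest called 11786 and set the library labelled KDAC4 H803A replicate 1 and KDAC7 H709A replicates 2, 3 and 4 against the other 3, which points to a structure of the libraries. The 2 sides differed in GC trend (-0.48 to -1.22 against 1.25 to 1.503), but after GC and length trends were removed KDAC7 H709A replicate 1 was still nearest to KDAC4 H803A replicate 3 (r of deviations 0.669, against -0.42 to -0.08 with its own group). For TMP195 against KDAC4 H803A there are only 10 splits, too few for a share under 0.05 (949, highest other 0). For genes set apart in KDAC4 H803A and in KDAC7 H709A 100 of 100 splits reached the real 0 of edgeR's tests (highest other 70 and 0; DESeq2 set apart 21 and 26). Counts of passing gene lists were reached by 11 of 35 splits for KDAC4 H803A against KDAC4 H976Y (8 lists, highest other 12), 17 of 35 for KDAC7 H709A against KDAC4 H803A (5, highest other 13), 8 of 35 for KDAC7 H709A against KDAC4 H976Y (10, highest other 13) and 43 of 100 for TMP195 against the variants (7, highest other 13). Chance was not excluded for any of these 4 list counts.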

How the results depend on the processing

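The offsets for GC content and length, with and without the library labelled KDAC4 H803A replicate 1, and the reading of all 15 columns as counts were chosen after the data were seen. Of 569 values of counts and correlations under an alternative 402 stayed within 1.5 times or the stated spread, and 167 moved. Of 2100 list results 1970 kept their side of the threshold and their direction, 68 came to pass, 61 ceased to pass and 1 reversed. Of 5926 results of named genes 5106 kept both, 816 ceased to pass and 4 reversed. Why a result moved was not tested under any of the alternatives. Another scaling moved the share of higher calls by under 10 percentage points, and GC and length offsets moved the median of all genes by -0.12 for TMP195 against KDAC4 H976Y.

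With 1 library left out, call counts ran from 1129 to 8431 for KDAC4 H803A against KDAC4 H976Y, 0 to 4788 for KDAC7 H709A against KDAC4 H803A, 1215 to 3440 for KDAC7 H709A against KDAC4 H976Y and 584 to 2761 for TMP195 against the variants. Against KDAC4 H803A, KDAC4 H976Y and KDAC7 H709A alone, TMP195 counts ran from 436 to 2695, 1307 to 5079 and 422 to 2755. Counts of at least 2-fold ran in the same order from 951 to 6516, 0 to 3587, 939 to 2128, 535 to 1697, 432 to 2248, 1147 to 3422 and 414 to 1978. Genes set apart ran from 0 to 995 for KDAC4 H803A, 442 to 1348 for KDAC4 H976Y, 0 to 255 for KDAC7 H709A and 243 to 631 for TMP195. Passing lists ran from 8 to 11, 3 to 8, 9 to 10 and 7 to 10 in the first 4 comparisons. Correlations against KDAC4 H976Y ran from 0.586 to 0.866 for KDAC4 H803A with KDAC7 H709A, 0.576 to 0.682 for KDAC4 H803A with TMP195 and 0.525 to 0.651 for KDAC7 H709A with TMP195. The low end of the first 2 and the highest counts of calls in 5 of the 7 comparisons belong to the fit without the library labelled KDAC4 H803A replicate 1.

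The DESeq2 Wald test called 4377 genes for KDAC4 H803A against KDAC4 H976Y, 79 for KDAC7 H709A against KDAC4 H803A (77 of at least 2-fold), 3394 for KDAC7 H709A against KDAC4 H976Y and 2839 for TMP195 against the variants. Against the single variants it called 1936 (1342 of at least 2-fold), 4493 and 2484 (1583 of at least 2-fold). It set apart 21, 1471, 26 and 859 genes for KDAC4 H803A, KDAC4 H976Y, KDAC7 H709A and TMP195. Without a filter on low counts, KDAC7 H709A against KDAC4 H803A had 14 calls, all 14 of at least 2-fold, and 2, 590 and 7 genes were set apart for KDAC4 H803A, KDAC4 H976Y and KDAC7 H709A. Fits of only the groups compared called 1634 genes for KDAC4 H803A against KDAC4 H976Y, 840 (703 of at least 2-fold) for TMP195 against the variants, 366 (366) against KDAC4 H803A and 9576 (4144) against KDAC4 H976Y. Splitting the KDAC4 H976Y libraries moved the first correlation to as low as 0.691. With an estimated correlation 0 lists passed in each of the first 4 comparisons, and with fry 0 passed for KDAC7 H709A against KDAC4 H803A.

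GC and length offsets gave 3370 calls for KDAC7 H709A against KDAC4 H976Y, 1434 genes set apart for KDAC4 H976Y and 8 lists for KDAC7 H709A against KDAC4 H803A. With the library labelled KDAC4 H803A replicate 1 also left out they gave 7431 calls for KDAC4 H803A against KDAC4 H976Y (4800.0 of at least 2-fold), 3250.0 for KDAC7 H709A against KDAC4 H803A (1946), 4597 for KDAC7 H709A against KDAC4 H976Y and 3144 for TMP195 against the variants. Against the single variants TMP195 then had 3770.0 (2533), 5413 and 2293 (1356). Genes set apart were 1236, 1813, 222 and 727, 8 lists passed for KDAC7 H709A against KDAC4 H803A, and the correlations were 0.66 for KDAC4 H803A with KDAC7 H709A and 0.532 for KDAC4 H803A with TMP195.

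Reading all 15 columns as counts gave a correlation of 0.683 for KDAC4 H803A with KDAC7 H709A, 13 and 8 passing lists in the comparisons of KDAC4 H803A with KDAC4 H976Y and with KDAC7 H709A, and turned the mitochondrially encoded mRNA list of the latter (median 0.064). Calls were 2 (2 of at least 2-fold) for KDAC7 H709A against KDAC4 H803A, 430.0 (414) for KDAC7 H709A against KDAC4 H976Y, 442 (425) for TMP195 against the variants and 612, 700.0 (688) and 288 (288) against the single variants. Genes set apart were 161 for KDAC4 H976Y, 1 for KDAC7 H709A and 200 for TMP195. In KDAC4 H803A against KDAC4 H976Y it reversed AKR1C3 (0.19), COL1A2 (0.31), SOX7 (0.29) and UNC13C (1.93). That column holds effective lengths, so these values describe a wrong unit.

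The replicate number as a block was run because the labels number the samples of each group, but the numbers do not pair them. Libraries with the same number in different groups had deviations that correlated at -0.084 on average (-0.687 to 0.3582, 19 pairs), against 0.024 for other pairs. With the block the counts were 1230.0 for KDAC4 H803A against KDAC4 H976Y (1033 of at least 2-fold), 1322 for KDAC7 H709A against KDAC4 H976Y (1000), 837 for TMP195 against the variants (692), 563 (526), 1556 (1320.0) and 453 (431) against the single variants, and 468 and 265 genes set apart for KDAC4 H976Y and TMP195.

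Low genes rest on few counts, since 1 CPM stands for 4.86 counts in the smallest library. In the simulation of KDAC4 H803A against KDAC4 H976Y 12% of 50 genes changed 2-fold were recovered. Depth was not varied and low genes were not tested apart, so their recovery is unknown.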

Other observations

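The genes and the tests of this part were chosen after their values were seen. PLAT, tissue plasminogen activator, had 394.7, 41.2, 47.0 and 461.0 CPM in KDAC7 H709A replicates 1 to 4, 426.4, 37.9 and 43.5 CPM in the libraries labelled KDAC4 H803A replicates 1 to 3, and 389.5 to 449.1 CPM in TMP195-treated cells. The transcription factor SOX4 had 21.04, 0.26, 0.06 and 24.4 CPM in the same KDAC7 H709A libraries and 23.3, 5.04 and 4.39 CPM in those of KDAC4 H803A. The cholesterol exporter ABCA1, on chromosome 9, had 1.45, 95.3, 98.7 and 5.11 CPM in KDAC7 H709A and 3.93, 92.0 and 70.9 CPM in KDAC4 H803A. The urea transporter SLC14A1 had 0.1, 37.9, 46.7 and 0.13 CPM in KDAC7 H709A and 0.19, 6.78 and 7.35 CPM in KDAC4 H803A, and the proteoglycan CSPG4 had 103.0, 2.34, 1.19 and 52.6 CPM in KDAC7 H709A and 52.8, 107.5 and 85.1 CPM in KDAC4 H803A. Thrombospondin THBS2, on chromosome 6 beyond 80 Mb, had 57.2, 13.7, 15.2 and 84.9 CPM in KDAC7 H709A and 82.4, 0.1 and 0 CPM in KDAC4 H803A. The chemokine CXCL8 had 19.8, 4.69, 5.07 and 46.4 CPM in KDAC7 H709A and 45.4, 0.48 and 0.66 CPM in KDAC4 H803A.

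Over the 198 expressed genes of chromosome 6 beyond 80 Mb the median deviation (log2, GC and length trends removed) was -0.49 and -0.50 in KDAC4 H803A replicates 2 and 3 and 0.14 in the library labelled replicate 1. It was 0.20, 0.18, 0.17 and 0.11 in KDAC7 H709A replicates 1 to 4, 0.20 to 0.21 in TMP195-treated cells and -0.07 to -0.11 in KDAC4 H976Y. Over the 310 genes before 80 Mb it was -0.14 to -0.18 in KDAC4 H976Y and -0.01 to 0.12 in the other libraries. Over all 508 genes of chromosome 6 the difference of KDAC4 H976Y from the other groups was -0.17 (-0.07 without removal of these trends), and the percentile of this median among 10000 random gene sets of the same size was 0, as for chromosomes 9 and 13. By windows of 20 Mb the difference was -0.30 at 20 to 40 Mb (171 genes), -0.25 at 40 to 60 Mb (67 genes) and between -0.35 and 0.09 in the others. On chromosome 6, 39 of 863 tested genes were set apart lower in KDAC4 H976Y and 7 higher (exact one-sided Fisher test, p = 0.0484, adjusted p = 0.278). On chromosome 9, 54 of 726 tested genes were set apart lower in KDAC4 H976Y and 5 higher (exact one-sided Fisher test for lower genes, p = 7.72e-08, adjusted p = 8.88e-07 over the chromosomes), and 81.8% of 400 expressed genes were lower there.

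The library labelled KDAC4 H803A replicate 1 and KDAC7 H709A replicate 4 differed by an overdispersion of 1.72, and 3 explanations were weighed. A shared GC and length trend is argued against by the correlation of their deviations, which was 0.958 after both trends were removed. A like response to loss of either enzyme should also hold for KDAC4 H803A replicates 2 and 3. Their lowest overdispersion against KDAC7 H709A replicate 4 was 149.2, which argues against it only if the labels of these libraries are right. The labels are in question here, so this explanation was not settled. A mislabelled sample stays open: the overdispersion of 1.72 is what it needs, but any other cause of the likeness gives the same, and these cannot be told apart because counts per gene do not show which variant the cells carried. With its own group KDAC7 H709A replicate 4 had 128.7, 22.5 and 16.99 (replicates 1 to 3), and the library labelled KDAC4 H803A replicate 1 had 149.2 and 156.9. KDAC7 H709A replicate 1 was nearest to another group too, but less closely (11.3 with KDAC4 H803A replicate 3, against 81.5 to 128.7 with its own). Its chromosome 6 median of 0.20 lay apart from -0.50 in that library. Which labels would be wrong, or whether the cells were separate clones, stays open.

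Lower expression over chromosome 13 in KDAC4 H976Y (median log2 difference -0.79) was weighed likewise, with 65 of 330 tested genes set apart lower there and 0 higher (exact one-sided Fisher test, p = 4.01e-31, adjusted p = 9.22e-30). A GC and length trend is argued against, because the median of -0.785 was taken after both were removed and was -0.591 before. A few lower genes are argued against by 95.8% of 168 expressed genes having a lower mean. Every window of 20 Mb with at least 10 genes had a median between -1.033 and -0.736, which is consistent with fewer copies of chromosome 13 in the KDAC4 H976Y cells as a hypothesis. Genes of 1 chromosome are not independent, and whether such a difference arose with the variant or in the cell line beforehand was not tested.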
